A study of Homo sapiens with 27 samples.

How the data were processed

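RNA was sequenced from 27 samples of human cell lines, 3 per group in 9 groups. Per the labels, total RNA was extracted with Trizol and a column kit and libraries were made with the NEBNext Ultra II kit, and the cell line, the ARID1A form and the shRNA of each sample were taken from its label. The deposited tables hold raw counts per gene, which the authors made from reads on genome build GRCh38. The authors name edgeR without a version, and their aligner, counting tool, annotation release, strand setting and filters are not stated, so reads shared between near-identical genes or read-through transcripts were assigned by rules that are not known here. The values were checked to be whole numbers with library totals from 33429483 to 55539529 for 293T and 59124374 to 79915177 for Huh7, and all columns matched a sample. Genes were placed with the GENCODE 29 annotation by gene identifier, and positions are given on GRCh38.

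Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling), with all groups of a cell line in 1 fit. Genes were kept with filterByExpr at its minimum count of 10 and minimum total count of 15, which left 23201 genes for 293T, 22510 for Huh7 and 23102 for the joint fit of both lines. The common biological coefficients of variation were 30.9%, 24.8% and 25.6%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes of a comparison. Pairs of replicate libraries differed with 11.7 to 345 times the variance expected from counting (chi-square per degree of freedom, 27 pairs). Pooled over genes, the spread between samples and not the depth thus sets the precision, while genes of low count were not examined apart. Standard errors are the absolute log2 difference divided by the square root of F. Per-library levels are TMM-scaled CPM, and log2 CPM used a prior count of 2.

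Before the data were examined, 13 comparisons and the difference of V2084D minus WT between the lines were fixed, along with 26 gene lists, the rule for named genes and the alternatives. The rule names ARID1A and STUB1, the 6 genes with the largest change in each direction in 4 comparisons (WT minus KO and V2084D minus WT in 293T, V2084D minus WT and shSTUB1 minus V2084D in Huh7) and 3 in each direction in the others. These had to be called, be named protein-coding genes, have a mean log2 CPM of at least 1 and show no overlap between the libraries of the groups. From each list described, up to 4 members with the smallest adjusted p were open to naming. CELF3, HSPA7 and AL158151.3 fall outside the rule and were chosen after their values were seen. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry, and p was adjusted over the lists of a comparison. Member counts are given over all genes and adjusted over the list alone. Of 144 list calls at the preset correlation, 15 held with an estimated correlation.

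The share of a difference kept or returned was measured on left-out libraries: genes were called on 2 libraries of each group, and the signed mean log2 difference was read in the left-out pair, in 9 ways, without ARID1A. Correlations of differences were set against 20 simulations of unchanged groups with the same shared libraries. Replicate numbers were taken as pairs only where deviations from the group mean correlated above 0.1 for every pair of libraries of equal number. This held for G2087E minus WT, G2087R minus WT and G2087E minus G2087R. Only for G2087R minus WT did every library's deviations correlate best with those of its own number, so the pairing of the others is uncertain. G2087R replicate 3 differed from replicates 1 and 2 with 316 and 345 times the variance expected from counting. The pairing for G2087R minus WT is therefore not established either. The main counts come from the unpaired fit, with the block as an alternative.

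Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fit of the compared groups only, each library left out in turn and a log2 difference of at least 1. Alternatives chosen after seeing the data were offsets for GC content and transcript length (known for 97.7% of the 293T and 97.9% of the Huh7 genes tested), alone and with the replicate block, a fit without the G2087R libraries that had ARID1A near the KO level, and a fit without K2025E replicates 2 and 3. Each comparison of 3 against 3 libraries was repeated for all 10 splits of its libraries, and the comparison between lines for 100 splits drawn at random. The pipeline was tested on simulated data with the measured means and spread. Its libraries were drawn independently, so it held none of the outlying libraries of the real data. Changes of single genes were put only into genes above a minimum mean CPM, so recovery at low counts was not measured. There 60 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were called for WT minus KO in 293T, and 90 and 99 for V2084D minus WT in Huh7. For the difference between the lines these were 26 and 98. A share of 50% put in was read as 49.5%, and the changed list was the 1 called of 26. The treatment text on the samples names Huh7 cells for all of them, and the cell line of each library is given here by its own label.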

Results

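Gene expression was measured by RNA sequencing in 27 samples of human cell lines in which the ARID1A gene had been knocked out. ARID1A encodes a large subunit of the BAF (SWI/SNF) chromatin remodelling complex. Per the labels, 18 libraries came from 293T, an embryonic kidney line carrying the SV40 large T antigen, and 9 from Huh7, a hepatocellular carcinoma line. The libraries labelled 293T fell into 6 groups of 3. They were knockout cells alone (KO) and knockout cells given back wild-type ARID1A (WT) or the missense mutants V2084D, G2087E, G2087R or K2025E. The libraries labelled Huh7 fell into 3 groups of 3: WT, V2084D, and V2084D together with a short hairpin RNA against STUB1 (shSTUB1). STUB1 encodes a ubiquitin ligase that works with HSP70 and HSP90 chaperones. Total counts ran from 33429483 to 55539529 per library labelled 293T and from 59124374 to 79915177 per library labelled Huh7, so the latter had the finer counting precision. Levels below are CPM (counts per 1000000) after TMM scaling, given as mean with SD over 3 libraries unless stated. Changes are log2 differences of the first group minus the second, with the standard error (SE) of the edgeR fit. The labels do not say whether replicates were separate cultures or clones, so the p-values measure only the spread between these samples, and a clone or pool used for 1 group cannot be separated from its genotype.

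ARID1A (ENSG00000117713, GRCh38 chromosome 1, positions 26693236 to 26782110, plus strand) was the gene altered by design. In the libraries labelled 293T its transcript stood at 148 CPM (SD 39.8) in KO. It was at 69944 CPM (SD 39177) in V2084D, 60072 CPM (SD 21626) in G2087E and 17539 CPM (SD 4143) in K2025E. The WT group was uneven: replicates 1, 2 and 3 had 5689.9, 9285 and 62916 CPM. The libraries labelled G2087R were more uneven still. Replicates 1 and 2 had 291 and 324 CPM, close to KO, and replicate 3 had 68169 CPM. ARID1A made up 0.013 to 10.6% of all counts in a library labelled 293T. In the libraries labelled Huh7 it was at 369 CPM (SD 28.99) in WT, 252 CPM (SD 31.2) in V2084D and 277 CPM (SD 81.8) with shSTUB1. That set has no library from knockout cells alone, so the part that came from the introduced gene could not be read from it. STUB1 (ENSG00000103266, chromosome 16, positions 680224 to 682870, plus strand) was at 168 CPM (SD 10.9) in 293T KO and at group means from 232 to 371 CPM in the other groups labelled 293T. These levels did not follow ARID1A: G2087R replicates 1 and 2, with little ARID1A, had 283 and 293 CPM, and WT replicate 3, with much, had 185 CPM.

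**Figure D1:**
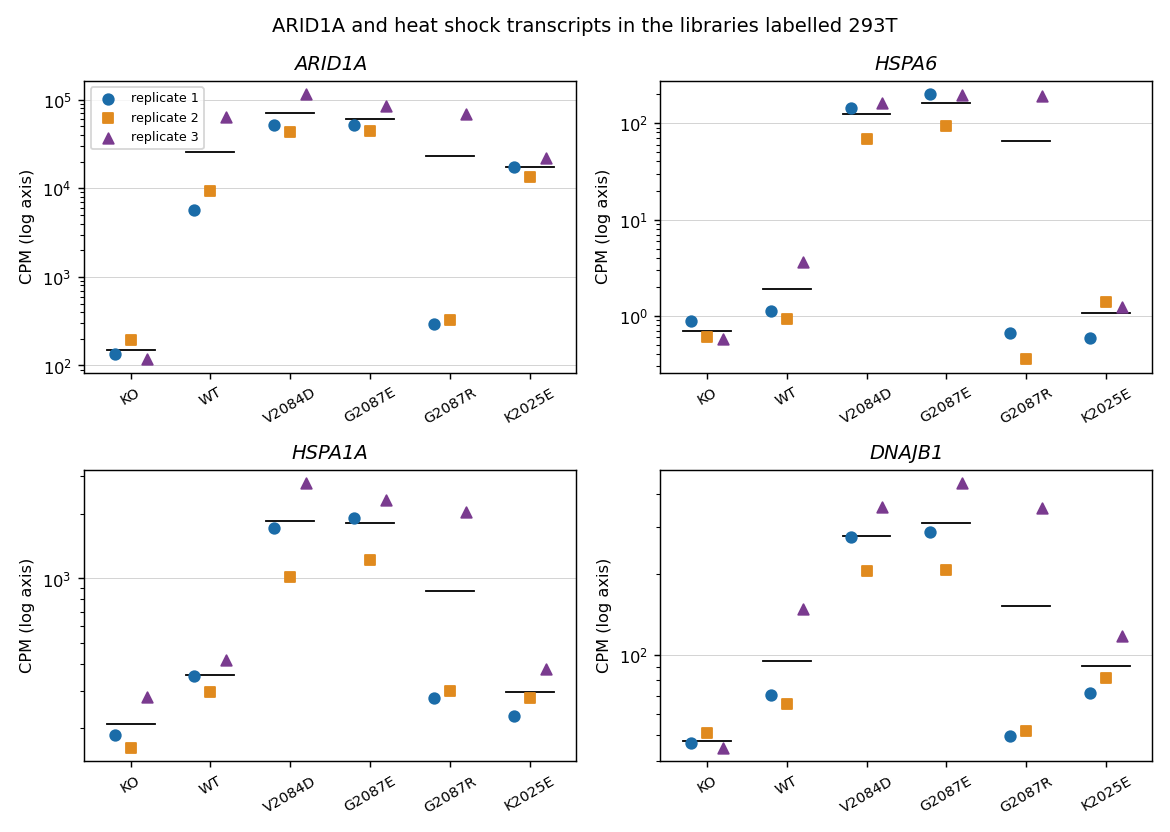
CPM of ARID1A, HSPA6, HSPA1A and DNAJB1 (log axes) in the 18 libraries labelled 293T, by group, with 1 point per library, shapes for the replicate number and a line at the mean of 3 libraries. HSPA6 sits between 68.4 and 199 CPM in the V2084D and G2087E libraries and at no more than 3.64 CPM in KO and WT and 1.39 CPM in K2025E. The G2087R libraries with little ARID1A also have little HSPA6.

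Markers of the cell types were read as a check of the material. Of 35 liver genes fixed in advance, 4 reached 10 CPM in any library labelled Huh7, and the same number did so in those labelled 293T. Albumin (ALB), the main plasma protein made by liver cells, had a mean of 0.639 CPM (SD 0.444, n = 9) in the libraries labelled Huh7 and 2.29 CPM (SD 0.883, n = 18) in those labelled 293T. Apolipoprotein B (APOB), carried by lipoproteins from the liver, had 0.81 CPM (SD 1.16) in the libraries labelled Huh7, and alpha-fetoprotein (AFP) had 0.0125 CPM (SD 0.0254). The 4 liver genes above 10 CPM were FOXA1, CEBPA, CPS1 and GPC3. Of 18 genes typical of 293 cells, 15 had a mean of at least 1 CPM in the libraries labelled Huh7 and 16 in those labelled 293T. MAP1B, a neuronal microtubule protein, was at 96.1 CPM (SD 19.6, n = 9) and 50.6 CPM (SD 11.3, n = 18). Spearman correlations between libraries of different cell line labels were 0.883 to 0.962 over 16213 genes, those between groups of the same label were 0.919 to 0.994 (293T) and 0.935 to 0.984 (Huh7), so the ranges overlap, and those within a 293T group were 0.957 to 0.993. Genes are not independent replicates in such a correlation.

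**Figure D2:**
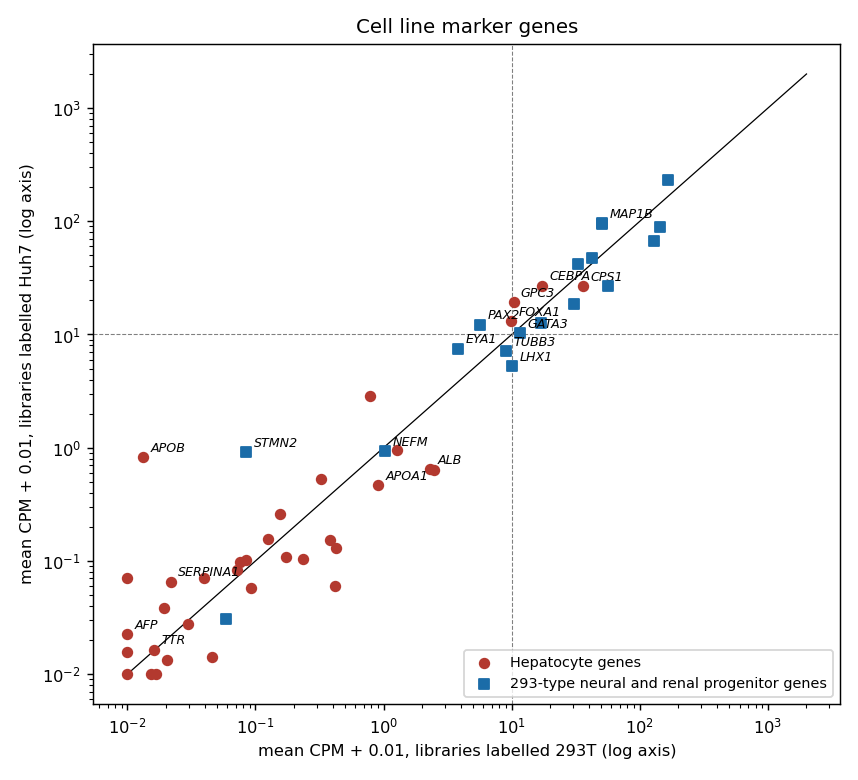
Mean CPM plus 0.01 of liver genes (circles) and genes typical of 293 cells (squares), in the 18 libraries labelled 293T (x axis) and the 9 labelled Huh7 (y axis), both log axes, with the line of equality and dashed lines at 10 CPM. Most genes of both lists lie near the line, and ALB lies below 10 CPM on both axes.

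Wild-type ARID1A against knockout in 293T asks which transcripts followed the return of the gene. No gene passed an adjusted p of 0.05 in edgeR, while 2544 of 23201 genes had an unadjusted p below 0.05 and DESeq2 called 81 (38 higher, 43 lower). ARID1A itself differed by 7.46 (SE 1.61, adjusted p = 0.343). The sets below were not called with an estimated correlation, and WT replicate 1 stood apart in the direction of the outlying K2025E libraries (first principal component -40.2, against -2.62 and 29.4 for replicates 2 and 3), so they may rest in part on that library. Ribosomal protein genes had a median of 0.55 over 32 members, none past the threshold over all genes and 32 higher when adjusted over the list alone. RPS27 differed by 0.73 (SE 0.209), RPS12 by 0.68 (SE 0.197) and RPLP0 by 0.54 (SE 0.170). That set had an adjusted p = 3.7e-22 with the preset correlation and an adjusted p = 0.162 with an estimated correlation. HOX genes, which set position along the body axis, had a median of -0.51 over 36 members, with 0 past the threshold over all genes and 21 lower when adjusted over the list alone. HOXD10 differed by -0.76 (SE 0.161), HOXB3 by -0.72 (SE 0.176) and HOXB8 by -0.69 (SE 0.185), and the set had an adjusted p = 0.162 with an estimated correlation. Proteasome subunits had a median of 0.37 over 31 members with 14 higher when adjusted over the list alone (PSMB6 0.68, SE 0.195; PSMB4 0.61, SE 0.180), and oxidative phosphorylation genes had a median of 0.37 with 7 higher in that way (NDUFB8 0.67, SE 0.218; NDUFS3 0.58, SE 0.187). G2/M genes of mitosis had a median of 0.30 and 9 higher when adjusted over the list alone, among them CENPA with 0.75 (SE 0.189) and UBE2C with 0.73 (SE 0.196). The proteasome and oxidative phosphorylation sets had an adjusted p = 0.162 with an estimated correlation, and the G2/M set an adjusted p = 0.309 with an estimated correlation. In simulated counts with the same spread, 60 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were called. Those libraries were drawn independently around a common mean per gene, apart from the changes put in, and held no outlying libraries. The changes were put only into genes above a minimum mean CPM, so recovery at low counts was not measured. ARID1A itself was not called at 7.46, so the absence of calls does not exclude large changes. A fit without G2087R replicates 1 and 2, chosen after the values were seen, called ARID1A (7.44, SE 0.789, adjusted p = 0.000342) and the uncharacterised transcript AL158151.3, which had 0 counts in all 3 WT libraries and 30 to 77 in KO. Over the 14 alternatives the adjusted p of ARID1A ran from 3.6e-08 to 0.78.

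V2084D and G2087E against knockout in 293T ask what the mutant proteins changed in cells without ARID1A. Besides ARID1A itself, a few heat shock genes, whose products refold damaged proteins, stood well above KO. HSPA6 (ENSG00000173110, chromosome 1, positions 161524540 to 161526910), an inducible HSP70 nearly silent in unstressed cells, was at 124 CPM (SD 48.8) in V2084D, 163 CPM (SD 60.5) in G2087E, 0.694 CPM (SD 0.176) in KO and 1.90 CPM (SD 1.51) in WT. HSPA1A, the main inducible HSP70, was at 1846 CPM (SD 891) and 1821 CPM (SD 564) in the mutants against 210 CPM (SD 62.9) in KO. DNAJB1, an HSP40 co-chaperone, was at 279 CPM (SD 75.0) and 311 CPM (SD 118) against 47.4 CPM (SD 3.30). With all 18 libraries in the fit, edgeR called 0 genes in either comparison, with 1120 and 1314 genes at an unadjusted p below 0.05, and DESeq2 called 29 and 38. HSPA6 then differed by 7.48 (SE 1.62, adjusted p = 0.918) for V2084D and by 7.87 (SE 1.64, adjusted p = 0.592) for G2087E. In the fit without G2087R replicates 1 and 2, chosen after the values were seen, 6 genes rose in each mutant and 0 fell. These were ARID1A, HSPA6, its neighbouring pseudogene HSPA7, HSPA1A, HSPA1B and DNAJB1 in both. There HSPA6 rose by 7.47 (SE 0.567, adjusted p = 3.8e-06) in V2084D and by 7.86 (SE 0.575, adjusted p = 2.1e-06) in G2087E, and DNAJB1 by 2.55 (SE 0.323, adjusted p = 0.00151) and 2.71 (SE 0.325, adjusted p = 0.000697). A fit of the 2 groups alone, fixed in advance, also called these 6 genes in both mutants. HSPA6 rose there by 7.47 (SE 0.394, adjusted p = 5.0e-05) in V2084D and by 7.85 (SE 0.364, adjusted p = 2.2e-06) in G2087E. DNAJB1 rose there by 2.54 (SE 0.209, adjusted p = 0.00213) and 2.70 (SE 0.243, adjusted p = 0.000832). Over the 14 alternatives the adjusted p of HSPA6 and DNAJB1 reached 1 in both mutants.

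As a set, the 28 heat shock genes had medians of 0.46 in V2084D and 0.48 in G2087E, with 8 members higher in each when adjusted over the list alone and 0 over all genes. The set had an adjusted p = 0.055 with an estimated correlation in V2084D and an adjusted p = 0.054 with an estimated correlation in G2087E. Integrated stress response genes, the targets of ATF4 in amino acid and protein stress, had medians of 0.25 and 0.27 over 24 members, with 3 and 5 members higher when adjusted over the list alone. CHAC1 differed by 0.95 (SE 0.279) in V2084D and by 1.24 (SE 0.280) in G2087E, ATF4 by 0.48 (SE 0.136) and 0.51 (SE 0.136), and SARS1 by 0.51 (SE 0.157) and 0.52 (SE 0.157). This set was also called with an estimated correlation (adjusted p = 0.046 in V2084D and 0.021 in G2087E). Against WT, CHAC1 in G2087E differed by 0.42 (SE 0.275), and CHAC1 in K2025E rose by 1.22 (SE 0.280) against KO. The rise is therefore not shown to be particular to V2084D and G2087E. With the replicate number as a block, HSPA1A and HSPA1B were the 2 genes called in each comparison. For G2087R against knockout, edgeR called 0 genes, 1001 had an unadjusted p below 0.05 and DESeq2 called 24. HSPA6 was at 193 CPM in G2087R replicate 3 and at 0.663 and 0.355 CPM in replicates 1 and 2, the libraries with ARID1A near the KO level. The HSPA6 difference of 6.54 (SE 1.56) became -0.46 without replicate 3, and 3 genes were then called.

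K2025E against knockout was the 1 comparison in 293T with many genes past the threshold: 1663 rose and 1326 fell. None of the set calls in this comparison held with an estimated correlation. All 32 ribosomal protein genes rose, with a median of 1.05 (RPS19 1.31, SE 0.229; RPS3 1.29, SE 0.215; RPL7A 0.92, SE 0.162). Of 31 oxidative phosphorylation genes 24 rose and 0 fell, 28 when adjusted over the list alone (NDUFB8 1.13, SE 0.220; UQCRQ 1.09, SE 0.206). Among 31 proteasome subunits 14 rose and 0 fell, 23 when adjusted over the list alone (PSMB6 1.08, SE 0.196; PSMB4 1.05, SE 0.181). Integrated stress response genes gave 6 that rose and 1 that fell of 24, including ATF4, its central transcription factor (0.86, SE 0.137), SARS1 (0.91, SE 0.158) and CHAC1 (1.22, SE 0.280), with 10 and 2 when adjusted over the list alone. With GC and length offsets the values of ATF4 and CHAC1 were 0.42 (SE 0.152) and 0.65 (SE 0.285) and their calls ended (adjusted p = 0.0884 and 0.157). Of 36 HOX genes 15 fell and 0 rose (HOXA6 -1.64, SE 0.349; HOXD10 -0.91, SE 0.161), 17 when adjusted over the list alone. Of 25 YAP/TEAD targets, genes of growth and cell contact, 8 fell and 0 rose (TEAD1 -1.28, SE 0.314; PTPN14 -1.21, SE 0.270), 9 when adjusted over the list alone. Of 13 transcripts encoded in mitochondrial DNA 6 fell and 0 rose (MT-ND4L -1.03, SE 0.244; MT-ND5 -0.92, SE 0.219), 9 when adjusted over the list alone. The ribosomal, oxidative phosphorylation and stress response sets each had an adjusted p = 0.16 with an estimated correlation, the proteasome and YAP/TEAD sets 0.19, the HOX set 0.25 and the mitochondrial set 0.31.

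Among single genes in that comparison, ARID1A rose by 6.89 (SE 1.57, adjusted p = 0.0111) and STUB1 by 1.14 (SE 0.249, adjusted p = 0.0095), from 168 to 371 CPM. P2RY11, a nucleotide receptor, rose by 2.56 (SE 0.490) and C11orf98 by 1.93 (SE 0.315). PROX1, a homeobox transcription factor, fell by 2.004 (SE 0.400). TPTEP2-CSNK1E fell by 3.03 (SE 0.441) and SYS1-DBNDD2 by 5.34 (SE 1.05), both read-through transcripts whose counts depend on how reads shared with the neighbouring genes were assigned. K2025E replicates 2 and 3 stood apart from the other libraries labelled 293T on the first principal component (-104 and -66.6, against -40.2 to 47.8 for the rest). A fit without both, chosen after the values were seen, leaves an arm of 1 library, so its count of 1 gene does not show what the calls rest on. Leaving out K2025E replicate 1, 2 or 3 gave 5270.0, 1 and 618 genes, and leaving out KO replicate 1 or 2 gave 1078 and 951. Without K2025E replicate 2 all 23 genes named for this comparison lost their calls, at adjusted p from 0.0617 to 0.101. Their values kept direction, with ARID1A at 7.02, P2RY11 at 2.87, HOXA6 at -1.64, RPS3 at 1.01 and STUB1 at 0.82. DESeq2 called 4605 genes, a fit of the 2 groups alone 436, and the replicate block 3605.

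Each group given a mutant was also set against wild type in 293T, which asks what the amino acid change did. For G2087R this holds for replicate 3 alone, since replicates 1 and 2 have little ARID1A transcript, so its values below are of the labelled group. The amount of ARID1A transcript differed as well. It was 5690 and 9285 CPM in WT replicates 1 and 2 and 42656 to 114835 CPM in the V2084D and G2087E libraries. The amino acid change is therefore not separated from that amount. V2084D and G2087E each gave 0 called genes in edgeR, with 467 and 475 at an unadjusted p below 0.05, and DESeq2 called 15 and 16. HSPA6 differed by 6.04 (SE 1.48) and 6.43 (SE 1.51), HSPA1A by 2.39 (SE 0.575) and 2.37 (SE 0.574), HSPA1B by 2.37 (SE 0.577) and 2.36 (SE 0.576), and DNAJB1 by 1.56 (SE 0.553) and 1.72 (SE 0.556). Without G2087R replicates 1 and 2, HSPA6, HSPA7, HSPA1A, HSPA1B and AL158151.3 were called higher in both mutants, HSPA6 by 6.05 (SE 0.520, adjusted p = 1.9e-05) in V2084D and 6.44 (SE 0.528, adjusted p = 8.5e-06) in G2087E. A fit of the 2 groups alone, fixed in advance, also called HSPA6, HSPA7, HSPA1A and HSPA1B higher in both mutants. HSPA6 differed there by 6.04 (SE 0.510, adjusted p = 0.000114) in V2084D and by 6.44 (SE 0.548, adjusted p = 0.00156) in G2087E. The adjusted p of HSPA6 reached 1 under other alternatives. Within the 28 heat shock genes 3 and 4 were higher when adjusted over the list alone, and the sets had an adjusted p = 0.61 with an estimated correlation in V2084D and an adjusted p = 0.46 with an estimated correlation in G2087E. ARID1A differed by 1.43 (SE 1.24) and 1.21 (SE 1.23). G2087R gave 1 called gene of the 1032 at an unadjusted p below 0.05, and DESeq2 called 27. This was CELF3, an RNA-binding protein of neurons, which fell by 2.55 (SE 0.367, adjusted p = 0.0367) and was named after its values were seen. Its call ended without G2087R replicate 1 (adjusted p = 0.0747) or replicate 2 (0.185) without WT replicate 2 (0.201) or replicate 3 (0.148), with GC and length offsets (0.148), and in a fit of the 2 groups alone (0.977). The value itself stayed between -2.83 and -2.19 in these fits. Over 14 alternatives its lowest adjusted p was 5.1e-08, and 18 genes were called without G2087R replicate 3. ARID1A differed by -0.18 (SE 1.22) for G2087R. With the replicate number as a block, the counts were 0 for G2087E and 1 for G2087R, and the block with GC and length offsets gave 0 and 88.

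K2025E against wild type gave 1 called gene of the 1919 at an unadjusted p below 0.05, and DESeq2 called 21. TPTEP2-CSNK1E fell by 3.64 (SE 0.450, adjusted p = 0.00415), from 16.1 CPM (SD 2.58) in WT to 1.29 CPM (SD 0.374). Without K2025E replicate 2 the value stayed at -3.49 and the call ended (adjusted p = 0.0941), with 0 genes called. It was -3.80 (adjusted p = 0.882) without replicates 2 and 3, a fit with an arm of 1 library that decides nothing about the call. In turn, 1048 genes were called without K2025E replicate 1 and 3 without WT replicate 3. Over 15 alternatives the adjusted p of this gene ran from 3.4e-14 to 0.882. The 32 ribosomal protein genes had a median of 0.44, with 7 higher when adjusted over the list alone (RPS3 0.73, SE 0.213; RPS23 0.66, SE 0.202) and an adjusted p = 0.37 with an estimated correlation. G2087E against G2087R, different changes of the same residue, gave 0 called genes in edgeR, 393 at an unadjusted p below 0.05 and 15 in DESeq2. HSPA1A differed by 1.06 (SE 0.552) and DNAJB1 by 1.04 (SE 0.546). Without G2087R replicate 3, the library of that group with ARID1A far above KO, 10 genes were called, and the replicate block gave 0.

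The mutants were compared with each other on the wild-type scale. The share of the WT minus KO difference that each mutant kept could not be given. Genes chosen on 2 WT and 2 KO libraries and read in the left-out pair differed there by -0.187 to 2.36, with no gene chosen in 2 of 9 ways and a difference at or below 0 in 3 of 9. With genes chosen at an unadjusted p below 0.01, the signed distance from KO was 0.175 in V2084D, 0.209 in G2087E, 0.0824 in G2087R and 0.565 in K2025E. The G2087R libraries gave 0.0244, 0.0303 and 0.192, and as replicates 1 and 2 have ARID1A near the KO level, their mean is no value for that mutant. The V2084D libraries gave 0.258, -0.0391 and 0.306, so that mean rests on how replicate 2 is read, and the mutants are not ranked here. Between pairs of mutants these gave exact two-sided permutation p from 0.1 to 0.8, where 0.1 is the smallest that 3 against 3 libraries can give, and 0.2 or more after adjustment over 6 pairs. Across 14332 genes, the V2084D and G2087E differences from WT correlated with r = 0.75, against 0.486 to 0.514 (mean 0.498) in 20 simulations of unchanged groups that share their WT libraries. Their covariance was 0.0378 against a simulated mean of 0.0401. The simulations treat libraries as independent, while libraries with equal replicate numbers went together in some of these comparisons, so whether the mutants share a change beyond the shared WT libraries is not settled. K2025E correlated with r = -0.29 with V2084D, -0.17 with G2087E and 0.0052 with G2087R, against simulated means of 0.499, 0.498 and 0.497. G2087R correlated with r = 0.523 with V2084D and 0.657 with G2087E, against 0.498 and 0.5002 (at most 0.515 and 0.521).

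V2084D against wild type in the libraries labelled Huh7 was among the largest differences of the series, with 4952 genes that rose and 4491 that fell of 22510, and 2528 changed at least 2-fold. Genes of the integrated stress response rose: 22 of 24 rose and 1 fell. Asparagine synthetase (ASNS, ENSG00000070669, chromosome 7, positions 97852118 to 97872542) went from 139 CPM (SD 5.15) to 867 CPM (SD 18.1), a rise of 2.64 (SE 0.0625, adjusted p = 3.9e-09). The mTORC1 inhibitor DDIT4 rose by 2.77 (SE 0.109), the glutathione-degrading enzyme CHAC1 by 2.34 (SE 0.0776) and the serine synthesis enzyme PSAT1 by 1.61 (SE 0.0621). Cholesterol synthesis genes fell: 21 of 25 fell and 0 rose, among them the synthesis enzymes NSDHL (-1.79, SE 0.0715) and DHCR7 (-1.75, SE 0.0726). Heat shock genes fell, 20 of 27 with 2 that rose. The constitutive HSP70 HSPA8 (ENSG00000109971, chromosome 11, positions 123057489 to 123063230) went from 2018 CPM (SD 4.11) to 275 CPM (SD 3.21), a change of -2.88 (SE 0.0459, adjusted p = 1.9e-10). HSPA1A changed by -3.42 (SE 0.0875), HSPA1B by -3.33 (SE 0.0737) and HSP90AA1 by -1.80 (SE 0.0485). These sets were called with the preset correlation and also with an estimated correlation (adjusted p = 0.0011, 0.0011 and 0.0015). The counts adjusted over the list alone were the same for the first and second sets and 21 that fell for heat shock.

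Other sets in this comparison passed the test with the preset correlation and not with an estimated one. All 11 list calls of this comparison held with fry. Of 36 HOX genes 28 fell and 2 rose (HOXB6 -1.66, SE 0.0911; HOXC9 -1.58, SE 0.0920), 29 and 2 when adjusted over the list alone, with an adjusted p = 0.078 with an estimated correlation. Of 30 ribosome biogenesis and MYC target genes 24 fell and 1 rose, the same number when adjusted over the list alone (NOP16 -1.24, SE 0.0637; NOP2 -1.06, SE 0.0679; adjusted p = 0.050 with an estimated correlation). Transcripts of mitochondrial DNA fell for 12 of 13, and for 13 when adjusted over the list alone (MT-CYB -1.25, SE 0.105; MT-CO3 -0.98, SE 0.0758; adjusted p = 0.24 with an estimated correlation). Interferon-stimulated genes of antiviral defence gave 18 that fell and 4 that rose of 38, the same when adjusted over the list alone (IFIT1 -1.99, SE 0.0685; OASL -1.83, SE 0.0945; adjusted p = 0.10 with an estimated correlation). Proteasome subunits gave 22 that fell and 1 that rose of 31, the same when adjusted over the list alone (PSMD1 -1.08, SE 0.0687; PSMD3 -1.02, SE 0.0786; adjusted p = 0.40 with an estimated correlation). Endoplasmic reticulum stress genes went both ways, 13 fell and 6 rose of 24, and 14 and 7 when adjusted over the list alone. The transcription factor XBP1 rose by 1.14 (SE 0.0774), while the chaperones CALR (-1.33, SE 0.0525), PDIA4 (-1.32, SE 0.0507) and HSPA5 (-1.09, SE 0.0563) fell, and the set had an adjusted p = 0.12 with an estimated correlation. BAF subunits gave 11 that fell and 2 that rose of 28, and 13 and 2 when adjusted over the list alone, including the ATPase SMARCA4 (-1.01, SE 0.0880) and ACTL6A (-0.90, SE 0.0627), with an adjusted p = 0.21 with an estimated correlation. Immediate early genes split, 10 rose and 13 fell, and the set was not called: ATF3 (3.12, SE 0.176) and JUN (2.44, SE 0.137) rose, and EGR1 (-4.23, SE 0.122) and JUNB (-1.31, SE 0.0752) fell.

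The largest rises among single genes of that comparison were in NUPR1, a stress-induced chromatin protein (4.43, SE 0.211), AFF2 (3.86, SE 0.321), TXNIP, an inhibitor of thioredoxin (3.76, SE 0.136), HAPLN2 (3.67, SE 0.252), CDRT4 (3.65, SE 0.749) and G0S2 (3.38, SE 0.238). The largest falls were in IRS4, an insulin receptor substrate (-4.58, SE 0.199; from 456 to 19.0 CPM), EGR1, FOS (-3.95, SE 0.417), HSPA1A, HSPA1B and the hyaluronidase HYAL3 (-2.97, SE 0.180). ARID1A changed by -0.55 (SE 0.183, adjusted p = 0.0325), a call that ended when any 1 of the 6 libraries was left out, whether V2084D replicate 1, 2 or 3 (adjusted p = 0.0614, 0.0578 and 0.119) or WT replicate 1, 2 or 3 (0.0529, 0.0758 and 0.107). It also ended with the replicate block (0.0575) and with no filter (0.0540), while the value stayed between -0.61 and -0.45 in these fits. Of 13 alternatives the lowest adjusted p was 0.000678, in a fit of the 2 groups alone. STUB1 differed by 0.21 (SE 0.0999, adjusted p = 0.115).

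**Figure D3:**
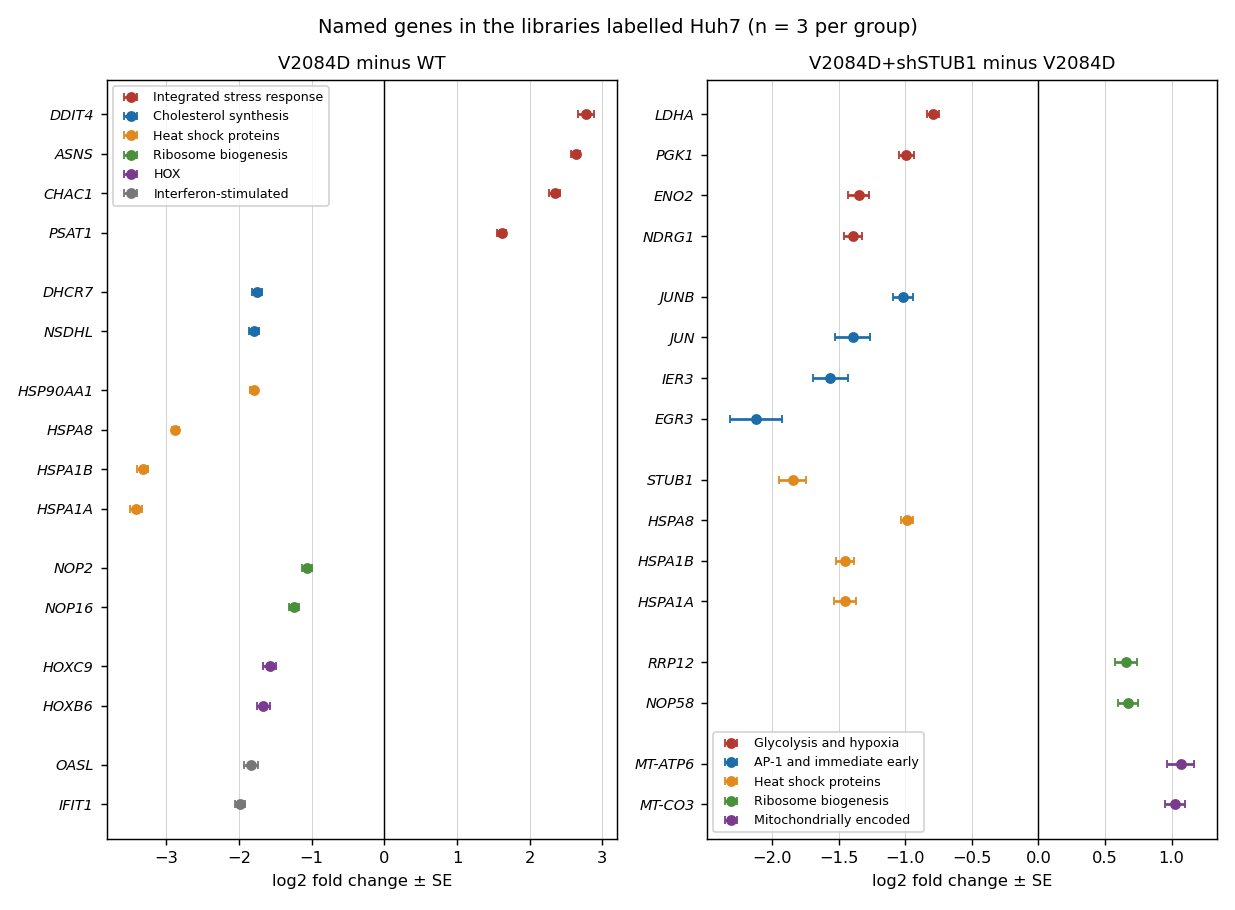
Log2 fold change with SE (x axis) of named genes, coloured by gene list, in the libraries labelled Huh7, for V2084D minus WT (left) and V2084D with shSTUB1 minus V2084D (right), with 3 libraries per group. ASNS at 2.64 and HSPA8 at -2.88 lie on opposite sides of 0 in the left panel, and HSPA8 lies at -0.99 in the right panel.

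V2084D with shSTUB1 against V2084D asks what lowering the ubiquitin ligase did in the mutant cells. The hairpin target fell: STUB1 went from 265 CPM (SD 26.9) to 73.8 CPM (SD 9.03), a change of -1.84 (SE 0.103, adjusted p = 8.8e-06), while ARID1A differed by 0.14 (SE 0.183, adjusted p = 0.668). In all, 2423 genes rose and 2427 fell, 658 of them at least 2-fold. Replicate 2 of shSTUB1 stood apart on the second principal component (-96.9, against -14.1 and -11.3) and had ARID1A at 189 CPM against 290 and 351 CPM, and 4359 genes were called without it. Glycolysis and hypoxia genes fell, 25 of 30 with 0 that rose and 26 when adjusted over the list alone: NDRG1 (-1.39, SE 0.0682), the enolase ENO2 (-1.35, SE 0.0789), PGK1 (-0.99, SE 0.0591) and lactate dehydrogenase LDHA (-0.79, SE 0.0456). Immediate early genes fell, 20 of 28 with 2 that rose, and 21 and 2 when adjusted over the list alone, among them EGR3 (-2.12, SE 0.193), IER3 (-1.56, SE 0.131), JUN (-1.40, SE 0.133) and JUNB (-1.01, SE 0.0754). Both sets were called with an estimated correlation as well (adjusted p = 0.012 and 0.036). Of 27 heat shock genes 9 fell and 0 rose, including HSPA1A and HSPA1B (-1.45 each, SE 0.0820 and 0.0690) and HSPA8 (-0.99, SE 0.0433), and 10 fell and 2 rose when adjusted over the list alone. That list holds STUB1 itself, the target of the hairpin, and had an adjusted p = 0.079 with an estimated correlation. Transcripts of mitochondrial DNA rose for 11 of 13, and for 12 when adjusted over the list alone (MT-ATP6 1.07, SE 0.101; MT-CO3 1.03, SE 0.0758; adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis genes gave 16 that rose and 1 that fell of 30, and 18 and 1 when adjusted over the list alone (NOP58 0.67, SE 0.0736; RRP12 0.66, SE 0.0800; adjusted p = 0.16 with an estimated correlation).

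G1/S genes of DNA replication gave 15 that rose and 4 that fell of 30, and 16 and 4 when adjusted over the list alone (CDC45 0.46, SE 0.0600; adjusted p = 0.32 with an estimated correlation). YAP/TEAD targets gave 8 that fell and 1 that rose of 25, and 10 and 2 when adjusted over the list alone (ANKRD1 -1.83, SE 0.330; CCN1 -0.88, SE 0.107; adjusted p = 0.23 with an estimated correlation). Among p53 targets TP53I3 rose by 1.49 (SE 0.163) and CDKN1A, a brake on the cell cycle, fell by 0.91 (SE 0.132), and that set was not called. The largest rises were in ZNF300 (1.51, SE 0.137), PRR22 (1.505, SE 0.203), TP53I3, the interferon gene IFNB1 (1.49, SE 0.224), ZNF582 (1.49, SE 0.299) and ZNF10 (1.39, SE 0.137). The largest falls were in the chemokine receptor CXCR4 (-2.54, SE 0.199), stanniocalcin STC1 (-2.27, SE 0.134), the metallothioneins MT2A (-2.13, SE 0.129) and MT1X (-2.10, SE 0.131), EGR3, and FLRT1 (-2.01, SE 0.244). The labels name 1 shRNA and no control hairpin, so an effect of the hairpin on other targets cannot be separated from that of STUB1. The count was 2887 without V2084D replicate 1 and 3140.0 without shSTUB1 replicate 1.

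V2084D with shSTUB1 against wild type asks how far the treated cells still stood from WT: 5282 genes rose and 4880 fell. Stress response genes gave 21 that rose and 1 that fell of 24 (ASNS 2.21, SE 0.0615; SLC7A11 2.19, SE 0.1003; CHAC1 1.79, SE 0.0763). Cholesterol genes gave 23 that fell and 1 that rose of 25 (INSIG1 -2.06, SE 0.0746; HMGCS1 -1.80, SE 0.0755). Heat shock genes gave 23 that fell and 1 that rose of 27 (HSPA1A -4.87, SE 0.0939; HSPA1B -4.78, SE 0.0790; HSPA8 -3.86, SE 0.0480). These counts were the same when adjusted over the list alone, and all of these sets were called with an estimated correlation (adjusted p = 0.0017, 0.00073 and 0.00073). HAPLN2 (4.04, SE 0.255), NUPR1 (3.84, SE 0.207) and AFF2 (3.75, SE 0.319) had the largest rises and FOS (-4.94, SE 0.442), HSPA1A and HSPA1B the largest falls. STUB1 changed by -1.63 (SE 0.103), and ARID1A differed by -0.42 (SE 0.183, adjusted p = 0.0901). Of the 9443 genes called for V2084D, 6928 were called in the same direction against WT with shSTUB1 and 2349 were not called.

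The share of the V2084D difference that shSTUB1 returned towards WT was measured on libraries not used to choose the genes. It was 0.128, with 0.0999 to 0.154 over 9 ways of leaving out 1 WT and 1 V2084D library, on 7247 to 9484 genes. In the left-out pairs WT lay 0.797 from V2084D on the signed log2 scale and shSTUB1 lay 0.103 from it. The values of the 3 shSTUB1 libraries were 0.0914, 0.104 and 0.113. Of genes called in both comparisons, 978 rose with V2084D and then fell with shSTUB1 and 1033 did the opposite, while 460 rose and 527 fell in both. The numbers from independent calls are 534, 483, 533 and 484, but the V2084D libraries enter both comparisons and push the calls towards opposite signs.

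The V2084D minus WT difference was also compared between the labelled cell lines in a joint fit of 12 libraries. It differed for 2778 of 23102 genes, with 1536 more positive and 1242 more negative in the libraries labelled Huh7. The joint fit uses 1 spread per gene for both lines. The stress response gene ASNS differed by 2.76 (SE 0.219). Over 13760 genes the differences in the libraries labelled 293T and Huh7 correlated with r = 0.0468. In 20 simulations with no change in either line, r was -0.0355 to 0.0452. The covariance was 0.0062, against at most 0.00239 in the simulations. The libraries labelled Huh7 had 9443 called genes, which the simulations do not hold, and simulated libraries are independent. The simulations therefore do not decide whether the lines share a change. The count of genes that differed was 4828 with GC and length offsets. It was 1708 to 1844 when any 1 of the 6 libraries labelled Huh7 was left out and 1822 without 293T V2084D replicate 1. ARID1A transcript levels also differed between these sets, as given above.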

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

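The tests of explanations and of other splits in this part were chosen after the results were seen, except the test of the 2 outlying K2025E libraries, whose outcome was set down before it was run. The difference between V2084D and WT was not the same in the libraries labelled Huh7 and 293T, by the test of the difference itself in a joint fit, for 2778 genes (1708 to 1844 without any 1 of the 6 libraries labelled Huh7, and 1822 without 293T V2084D replicate 1). The most positive values were in NUPR1 (4.90, SE 0.564), TXNIP (4.50, SE 0.464) and HAPLN2 (3.76, SE 0.468), which rose in the libraries labelled Huh7. The most negative were in HSPA6 (-6.70, SE 0.655), HSPA1A (-5.79, SE 0.385) and HSPA1B (-5.69, SE 0.361), inducible HSP70 genes. The joint fit uses 1 spread per gene for both lines. In the fit of the 293T groups, V2084D minus WT had SE 1.48, 0.575 and 0.577 for these genes, and none was called. Among gene sets, the median difference was -0.98 for heat shock genes (16 of 28 called negative), 0.99 for integrated stress response genes (16 called positive and 1 negative of 24) and -0.75 for cholesterol synthesis genes (13 of 25 negative). It was -0.66 for ribosome biogenesis genes (16 of 30 negative) and -0.38 for interferon-stimulated genes (6 negative and 1 positive of 38). These 5 sets were also called with an estimated correlation. Of 100 splits, 14 gave as many genes, the real one included, and the highest other gave 5639, so chance is not excluded by this test. Each of the 13 others kept the real grouping of the libraries labelled Huh7 and reshuffled those labelled 293T, and splits that broke that grouping gave at most 2, so the splits point to the Huh7 grouping as the structure behind the count.

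The heat shock genes HSPA6, HSPA1A, HSPA1B and DNAJB1 stood above KO and WT in the V2084D and G2087E libraries of 293T, while most of the 28 genes of that list did not stand out. Reads shared between near-identical HSPA genes are argued against as the whole cause, since DNAJB1, a gene of another family, rose by 2.55 (SE 0.323) for V2084D minus KO in the fit without G2087R replicates 1 and 2. A batch of libraries numbered 3 is argued against by replicates 1 and 2 of both mutants, where the lowest HSPA6 level was 68.4 CPM. The amount of ARID1A transcript stays open: HSPA6 was at 3.64 CPM in the only WT library with ARID1A in the range of these mutants, and 1 library does not decide. A candidate explanation is that the mutant proteins themselves call up the heat shock response, a hypothesis found and tested on the same libraries. V2084D in the libraries labelled Huh7 went with a fall of HSPA1A by 3.42 (SE 0.0875) and HSPA1B by 3.33 (SE 0.0737). ARID1A was at 252 CPM (SD 31.2) there, below the 291 and 324 CPM of G2087R replicates 1 and 2 in 293T. With no KO library in that set, expression of the mutant is not shown, so the fall does not decide on this explanation. K2025E in 293T did not show the rise either, with HSPA6 at no more than 1.39 CPM and HSPA1A at 295 CPM (SD 77.3). ARID1A was at no more than 21658 CPM in K2025E and at least 42656 CPM in V2084D and G2087E. K2025E therefore does not separate the kind of mutant from the amount of ARID1A transcript. G2087R replicate 3 had ARID1A at 68169 CPM and HSPA6 at 193 CPM, against 62916 and 3.64 CPM in WT replicate 3, each a single library. More WT libraries with ARID1A in the range of the mutants would be needed to decide.

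The genes called for K2025E minus KO were weighed against bias and against K2025E replicates 2 and 3, which stood apart from the other libraries. With offsets for GC content and length, which moved the median of all genes by -0.12, 1471 of the 2989 called genes kept call and sign and 2486 were called in all, so such a bias does not make up the whole pattern. Genes chosen on replicates 2 and 3 (3232 to 5435) lay on average 0.34 from the left-out KO library in K2025E replicate 1, in the chosen direction, below the 0.606 of WT replicate 1 and above the 11 other libraries of the groups with no calls (at most 0.295). The pattern may therefore rest on the 2 outlying libraries in part or whole, and whether these differ by culture, by sample handling or by the mutant was not tested.

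Liver transcripts were close to absent from the libraries labelled Huh7, a line of liver origin. Omission of liver genes by the counting is argued against, since 32 of 35 liver genes had a count in these libraries. A mislabelled cell line is consistent with the values: 4 liver genes reached 10 CPM in them, no more than in the libraries labelled 293T, and 15 of 18 genes typical of 293 cells had a mean of at least 1 CPM. Loss of liver transcripts in the knockout cells is a biological explanation that stays open, because no library labelled Huh7 comes from cells with their own ARID1A.

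Other splits of the same 6 libraries were counted for each comparison, and 10 splits cannot give a share under 0.05. For the comparisons with KO in 293T, WT, V2084D, G2087E and G2087R gave 0 genes, so all 10 splits gave as many, with at most 1, 1, 2 and 1 genes in another split. K2025E minus KO gave 2989 genes against at most 2 in another split, and 1 of 10 splits was as large. Against WT, V2084D and G2087E gave 0 genes in all 10 splits. G2087R gave 1 gene against at most 0, with 1 of 10 splits as large, and K2025E 1 gene against at most 1639, with 2 of 10 splits as large. That split set K2025E replicate 1 with WT replicates 2 and 3, which points to a structure of the samples with K2025E replicates 2 and 3 and WT replicate 1 on the other side. G2087E minus G2087R gave 0 genes and another split 3, so all 10 gave as many. In the libraries labelled Huh7, V2084D minus WT gave 9443 against at most 1, shSTUB1 minus V2084D gave 4850.0 against at most 2, and shSTUB1 minus WT gave 10162 against at most 1, each with 1 of 10 splits as large.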

How the results depend on the processing

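The alternatives fixed in advance and those chosen after seeing the data (GC and length offsets, alone or with the block, and the fits without G2087R replicates 1 and 2 or K2025E replicates 2 and 3) changed the counts as follows, and the cause was not tested unless stated. RLE size factors, no filter and a filter of 1 CPM in 3 libraries kept all counts within 1.5 times. DESeq2 gave 81 genes for WT minus KO, 29 for V2084D, 38 for G2087E, 24 for G2087R and 4605 for K2025E minus KO. It gave 15, 16, 27 and 21 for V2084D, G2087E, G2087R and K2025E minus WT, and 15 for G2087E minus G2087R. A fit of the compared groups alone, which estimates the spread from fewer libraries, gave 5, 7, 8 and 436 for WT, V2084D, G2087E and K2025E minus KO, and 10, 7 and 5 for V2084D, G2087E and K2025E minus WT. Without G2087R replicates 1 and 2 the counts were 2, 6 and 6 for WT, V2084D and G2087E minus KO, and 5, 5 and 2 for V2084D, G2087E and K2025E minus WT. The replicate block gave 2 genes each for V2084D and G2087E minus KO, 3605 for K2025E minus KO, and 8750.0, 3992 and 9411 for V2084D minus WT, shSTUB1 minus V2084D and shSTUB1 minus WT in Huh7. For the paired comparisons the block gave 0 for G2087E minus WT, 1 for G2087R minus WT and 0 for G2087E minus G2087R, and with GC and length offsets 0, 88 and 0. It gave 1 for K2025E minus WT, 0 for V2084D minus WT, 0 for WT and G2087R minus KO, and 2389 for the difference between the lines. GC and length offsets gave 1 for WT minus KO, 0 for G2087R minus WT and 4828 for the difference between the lines. Without K2025E replicates 2 and 3, an arm of 1 library, K2025E minus KO gave 1 gene. A change of at least 2-fold left 984 for K2025E minus KO, 2528, 658 and 2934 for the Huh7 comparisons in the order above, and 1645 for the difference between the lines, fewer by construction. Leaving out 1 library gave 0 to 0 for WT, V2084D and G2087E minus KO and for V2084D and G2087E minus WT, and 0 to 3 for G2087R minus KO (highest without G2087R replicate 3). It gave 1 (without K2025E replicate 2) to 5270.0 (without K2025E replicate 1) for K2025E minus KO, with 618 without replicate 3 and 1078 and 951 without KO replicate 1 or 2. It gave 0 to 18 for G2087R minus WT (0 without G2087R replicate 1 or 2 or WT replicate 2 or 3, 18 without G2087R replicate 3) and 0 (without K2025E replicate 2) to 1048 (without K2025E replicate 1) for K2025E minus WT, with 3 without WT replicate 3. It gave 0 to 10 for G2087E minus G2087R (highest without G2087R replicate 3). In Huh7 it gave 8030.0 to 8675 for V2084D minus WT, 2887 to 4505 for shSTUB1 minus V2084D (lowest without V2084D replicate 1, 3140.0 without shSTUB1 replicate 1) and 8724 to 9751 for shSTUB1 minus WT. For the difference between the lines it gave 1708 (without Huh7 V2084D replicate 2) to 3448, with 1822 without 293T V2084D replicate 1, 1734 and 1844 without Huh7 V2084D replicate 1 or 3, and 1777, 1774 and 1715 without Huh7 WT replicate 1, 2 or 3. The returned share of 0.128 moved to 0.160 with genes changed at least 2-fold and to 0.107 with the median, and stayed within the spread of its libraries (SD 0.0135) under RLE, no filter, an adjusted p below 0.001 and an unadjusted p below 0.01. The kept shares in 293T are not reported under any setting, since the held-out WT minus KO difference was at or below 0 in 3 of 9 ways, and in 1 of 9 with genes at an unadjusted p below 0.01. The named values that turned direction were not called: HSPA6 for G2087R minus KO (-0.46 without G2087R replicate 3 to 7.12), ARID1A for G2087R minus WT (-6.40 without G2087R replicate 3 to 1.62 without WT replicate 3), ARID1A for K2025E minus WT (0.33 with the block, -1.04 to 1.22 without WT replicate 1 or 3) and ARID1A for shSTUB1 minus V2084D (-0.070 to 0.35 without shSTUB1 replicate 3 or 2). Of 1104 values of named genes with 1 library left out, 1050.0 kept direction and call, 41 lost and 7 gained a call, and 6 turned. DESeq2 kept 158 of 177 and gained 19, RLE kept 177, and GC and length offsets kept 172, lost 3 and gained 2. A fit of the 2 groups alone kept 149 of 170.0, lost 4 and gained 17, and the replicate block kept 171, lost 1, gained 4 and turned 1. The fit without G2087R replicates 1 and 2 kept 51 of 68 and gained 17. Of 144 list calls, 15 held with an estimated correlation, 65 with fry, 137 with GC and length offsets, 143 with the block and 144 with RLE, none reversed. Fry kept all 11, 10 and 14 list calls of the Huh7 comparisons in the order above. It kept 11 of 14 for K2025E minus KO, 6 of 13 for WT minus KO and 0 for each mutant minus WT in 293T. Pooled over genes, replicates differed with at least 11.7 times the variance expected from counting, so depth limits little for the abundant genes that weigh most there. Genes of low count were not examined apart.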

Other observations

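The remaining gene sets of V2084D with shSTUB1 against WT in the libraries labelled Huh7 are given as values. Interferon-stimulated genes gave 18 that fell and 3 that rose of 38, and 18 and 4 when adjusted over the list alone. IFIT1 fell by 2.16 (SE 0.0689) and HERC5, an antiviral ligase for ISG15, by 1.76 (SE 0.0609), with an adjusted p = 0.053 with an estimated correlation for the set. Glycolysis and hypoxia genes gave 20 that fell and 3 that rose of 30, and 21 and 4 when adjusted over the list alone (PFKP -1.44, SE 0.0698; PKM -1.26, SE 0.0487; adjusted p = 0.082 with an estimated correlation). HOX genes gave 27 that fell and 2 that rose of 36, the same when adjusted over the list alone (HOXB6 -1.91, SE 0.0919; HOXC9 -1.90, SE 0.0930; adjusted p = 0.057 with an estimated correlation). G2/M genes gave 17 that fell and 8 that rose of 32, the same when adjusted over the list alone, with an adjusted p = 0.25 with an estimated correlation.

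The uncharacterised transcript AL158151.3 (ENSG00000235007), chosen after its values were seen, had 0 counts in the 3 WT libraries labelled 293T and in G2087R replicate 3. A count of 0 allows up to 3 counts. The 14 other libraries labelled 293T had 30 to 108 counts each.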
